A study of Mus musculus with 9 samples.

How the data were processed

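PRO-seq libraries from 9 samples of mouse embryonic stem cells were used, 3 at each of 0, 15 and 30 min of doxycycline. The dose was 1 ng/μL at 15 and 30 min and 0 ng/μL at 0 min. The genotype was a Firre knockout with an inducible Firre transgene. The nuclei were mixed with 1% Drosophila S2 nuclei per the labels. Counts of the Drosophila nuclei were not used here, so all changes are relative to the other mouse regions. No sample received doxycycline without the transgene, so the effect of the drug itself was not separated from that of the transgene. Sample names in the count table matched the titles for all 9 libraries.

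The deposited table holds raw read counts for 174289 bidirectional regions, and the deposited region lists give other values, the start and end of each region on mm10. The file names name Tfit and muMerge for the regions. The authors' processing notes name HISAT2, featureCounts and DESeq2 1.26.0 without stating their settings or the strand counted. All counting windows were 600 bp wide, and 50841 (29.2%) overlapped another window. The library total is the number of reads in the regions, 3813365 to 5980366, and not the sequenced depth.

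Regions were named from a gene annotation of GRCm38, the same assembly as mm10. Its table gives no strand, so a region was said to lie at a gene end when its centre was within 1 kb of either annotated end of a gene, in place of a transcription start site. Of 49943 annotated genes on these chromosomes 35108 were used for naming. No genome sequence was at hand, so base composition and motifs were not analysed here.

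Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables were prepared in Python 3.11.15. Regions with low counts were removed by edgeR's default expression filter on the groups (119990 removed, 54299 tested), and libraries were scaled with TMM factors, between 0.971 and 1.02. All 9 libraries entered 1 quasi-likelihood fit with time as a factor, so the groups shared an estimate of the spread (common dispersion 0.0228). Contrasts were 15 against 0 min, 30 against 0 min, 30 against 15 min, and both times together. P-values were adjusted by Benjamini-Hochberg over all tested regions and called at 0.05. The SE of a log2 change is its size divided by the square root of the F statistic. CPM values are scaled by TMM.

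Regions were named by a rule set before the data were examined, as were the comparisons, their main tests, gene lists and most alternatives. Tests of the patterns described near the end were added once the patterns had been seen. The naming rule took every Firre region. For each contrast it also took the 12 higher and 12 lower called regions of largest change. These came from regions with a mean of at least 20 counts over the libraries compared, whose groups did not overlap in CPM (a gene counted once). For each gene list it took the 3 members with the smallest p at 30 against 0 min. Where a Firre or Gm35612 region had few reads at 0 min, a ratio of summed counts with an exact Poisson interval at the 95% level is given.

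Shares of called regions away from gene ends and on the X chromosome were tested by Fisher's exact test, two-sided, and adjusted over 9 tests. The overlap of the 15 and 30 min calls was set beside the product of the call rates and beside 20 simulations without any change. In these, all libraries were redrawn from means common to all times, and both comparisons shared the redrawn 0 min libraries.

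The 31 gene lists were tested with camera at a preset correlation of 0.01 on regions at gene ends, using for each gene its region with the highest mean count (18069 genes with a region, 13693 tested). The p-values were adjusted over 93 tests. The lists were written from general knowledge and not checked against a database. The lists were naive, core, and formative and primed pluripotency, the two-cell-like state, primitive endoderm, mesoderm, neuroectoderm, trophectoderm, feeder fibroblasts, immediate early genes, YAP and SRF targets, the integrated stress response, the mitochondrial ribosome, heat shock, and the unfolded protein response. The others were p53, NF-kB and interferon, LIF-STAT3, WNT, and NOTCH, TGF-beta and BMP targets, MYC-driven ribosome biogenesis, cytosolic ribosomal proteins, histones, cholesterol synthesis, glycolysis and hypoxia, G1/S, G2/M, lncRNA genes, Firre contact genes, Firre binding partners, and Polycomb factors.

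Alternatives were DESeq2 size factors, library size alone, TMM factors from regions at gene ends alone, no filter, a filter of 20 counts in 3 libraries, only the 2 groups compared, the replicate number as a block, the DESeq2 Wald test, windows that overlap no other, a 500 bp limit for gene ends, and each of the 9 libraries left out in turn. For lists they also included an estimated correlation, fry, and the sum over a gene's regions. Counting a shared region once in a list and leaving Firre and Gm35612 out of the X share were chosen after seeing the data. The steps were tested on simulated data made with known changes in 100 regions per fold size. At 15 against 0 min, 8 of 100 regions changed by 1.5-fold and 62 of 100 changed by 2-fold were recovered among 51778 tested, with 7 false calls of 77. At 30 against 0 min 11 and 67 of 100 were recovered among 51829 tested, with 8 false calls of 86. In simulated lists the 1 shifted list was called and 0 of 30 unshifted lists were. The genes of these lists were drawn independently of each other. The simulation therefore cannot show how the preset correlation performs where the genes of a list vary together.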

Results

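The series measured nascent transcription by PRO-seq, a run-on assay that maps engaged RNA polymerase, in mouse embryonic stem cells. The cells lacked Firre, an X-linked gene for a nuclear long non-coding RNA, and carried a Firre transgene switched on by doxycycline. Cells were collected untreated (0 min) and at 15 and 30 min after 1 ng/μL doxycycline. Each time had 3 libraries, numbered below by the replicate number in their titles. The measured units were 174289 bidirectional regions, places where transcription leaves in both directions, each counted in a window of 600 bp on the mm10 build. Of these, 24953 (14.3%) were centred within 1 kb of an annotated gene end, 73765 (42.3%) lay inside a gene and 75571 (43.4%) lay outside genes. Reads in the regions came to 5518443, 4426619 and 3813365 for libraries 1 to 3 at 0 min. They came to 5980366, 5262335 and 4239213 at 15 min and to 5398120, 5394519 and 4279835 at 30 min. A count of 3 equals 0.502 to 0.787 CPM (counts scaled to library size) across the libraries, and all counting intervals below cover counting error only. Counts of replicate libraries differed by more than sampling noise, with chi-squared per degree of freedom of 2.26 to 3.78, and the fitted coefficient of variation between replicates was 15.1%. On the second principal component (13.9% of the variance), 15 min library 3 lay apart from the other 8, at -83.0. The labels do not say whether the 3 libraries of a time came from separate cultures, so the p-values measure the spread between these libraries, which may be technical in part.

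The first question was whether doxycycline switched on the transgene, read at the annotated Firre gene (X:50563120 to 50635321, 72.2 kb). Summed over its 8 regions, Firre signal was 3.34 ± 1.37 CPM at 0 min, 295 ± 37.1 CPM at 15 min and 785 ± 7.33 CPM at 30 min (mean ± SD, n = 3 libraries each). The ratio to 0 min was 88.4 at 15 min and 235 at 30 min. The region bidir_167537 (X:50569537 to 50570136), inside Firre, rose by a log2 of 6.67 ± 0.22 (SE) at 15 min and 8.06 ± 0.21 at 30 min (adjusted p = 3.04e-17 and 1.37e-19). bidir_167538 rose by 6.04 ± 0.24 and then 7.45 ± 0.23, and bidir_167541 by 5.92 ± 0.35 and then 7.41 ± 0.32. The other 4 tested Firre regions had 1 to 3 reads in all at 0 min, so ratios of summed counts with 95% counting intervals are given for them.

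At bidir_167535, beside the end of Firre, the ratio was 200 (68.2 to 973) at 15 min and 520 (177 to 2520) at 30 min. At bidir_167536 it was 61.0 (20.6 to 298) and 135 (45.8 to 655), and at bidir_167539 it was 100 (34.0 to 489) and 304 (104 to 1480). At bidir_167542 it was 25.4 (4.20 to 1040) and 92.4 (16.2 to 3690). bidir_167540 had 0 reads in every library and was not tested. Its window overlaps that of bidir_167539, which had 332 reads in all at 15 min and 987 at 30 min. The 0 therefore cannot be read as absence of transcription, as the counting of overlapping windows is not known. The windows of bidir_167537 and bidir_167538 also overlap, so the summed Firre signal may count some reads more than once. All 7 tested Firre regions were called at 15 min and at 30 min, over all regions and adjusted over the list alone. From 15 to 30 min 6 of the 7 were called higher over all regions, and 7 of 7 adjusted over the list alone. bidir_167542, at a log2 of 1.79 ± 0.46, missed the call over all regions (adjusted p = 0.0701) and had adjusted p = 0.000602 over the list alone. The rise of bidir_167536 from 15 to 30 min (log2 1.12 ± 0.20) was not called without 15 min library 1 or without 30 min library 2. DESeq2 did not call bidir_167542 at either time against 0 min. Beside Firre, inside the annotated gene Gm35612, bidir_167533 had a ratio to 0 min of 75.8 (32.2 to 235) at 15 min and 160 (68.3 to 494) at 30 min. At bidir_167534, also inside Gm35612, the ratios were 74.0 (25 to 362) and 178 (60.6 to 866). The position of the transgene was not analysed here, and reads placed here can come from it only where its sequence is the same.

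**Figure D1:**
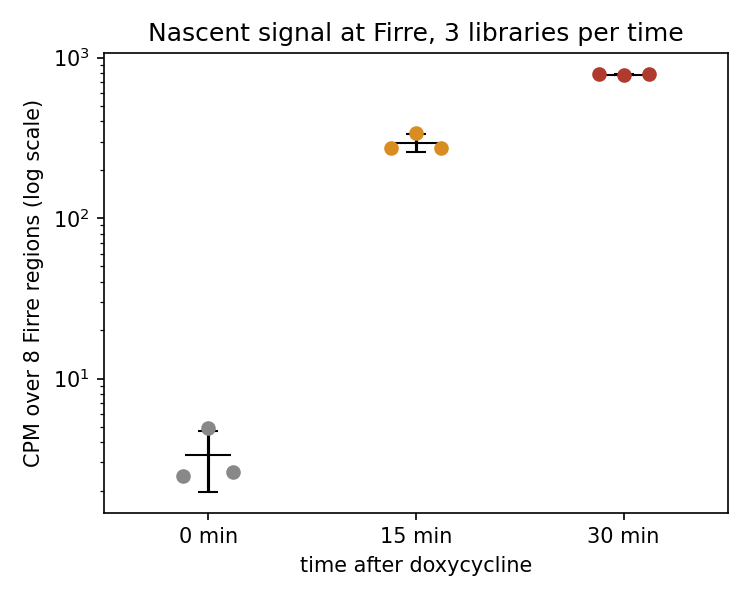
Reads over the 8 annotated Firre regions in CPM on a log axis, one point per library, with bars for the mean and SD of 3 libraries at each time after doxycycline. The means were 3.34 CPM at 0 min, 295 CPM at 15 min and 785 CPM at 30 min.

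The comparison of 15 min with 0 min asked which regions changed first. Outside the Firre locus, the largest rises under the naming rule lay away from gene ends. A region inside Eml6, which encodes a microtubule-associated protein (11:29762917 to 29763516), rose by a log2 of 3.45 ± 0.34 (SE, n = 3 libraries per time, adjusted p = 3.17e-07), and one inside Dupd1, a dual-specificity phosphatase gene, by 3.17 ± 0.22. Regions outside genes rose by 3.04 ± 0.38 at 12.5 kb from Slc45a3, a solute carrier gene, and by 2.82 ± 0.21 at 6.96 kb from Trps1, which encodes a GATA-type repressor. A region inside Fads3, of the fatty acid desaturase family, rose by 2.79 ± 0.23. Regions nearest to Arih1 and Trip12, genes of ubiquitin ligases, rose by 2.68 ± 0.23 and 2.40 ± 0.26. Regions nearest to Orc5 (origin recognition), Arhgap5 (GTPase activation) and Actr5 (INO80 chromatin remodelling) rose by 2.60 ± 0.24, 2.48 ± 0.19 and 2.45 ± 0.37. Of the 12 named regions that rose, 0 lay at a gene end, 5 inside a gene and 7 outside genes.

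The named regions that fell at 15 min lay more often at gene ends. At the gene ends of Aifm2, a suppressor of ferroptosis, of the Polycomb gene Cbx8, of Unc13a (synaptic vesicle priming) and of Zkscan16 (a zinc finger protein), the log2 changes were -1.81 ± 0.34, -1.70 ± 0.33, -1.69 ± 0.22 and -1.77 ± 0.31. At those of Megf6, Tpcn1 (a two-pore channel) and Kif3c (a kinesin) they were -1.69 ± 0.35, -1.66 ± 0.26 and -1.66 ± 0.33. Inside Gm34121, inside Stim1, the calcium sensor gene of the endoplasmic reticulum, and inside Kcng1 they were -1.97 ± 0.27, -1.94 ± 0.35 and -1.91 ± 0.35. The regions nearest to Gm26747 (43.8 kb) and Btbd2 (2.26 kb), outside genes, gave -1.97 ± 0.34 and -1.84 ± 0.31. All 24 named regions were called without any 1 of the 9 libraries.

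In all, 4479 of 54299 tested regions (8.25%) were called at 15 min against 0 min by edgeR's quasi-likelihood test, 2331 higher and 2148 lower, and 1769 of them by more than 2-fold. DESeq2 called 3650, of which 3568 were shared, and 12586 regions had an unadjusted p under 0.05. With scaling factors set on regions at gene ends alone, the median of all regions moved from 0.03 to 0.19 on the log2 scale and the calls became 4135 higher and 968 lower, so that the split by direction (52.0% higher against 81.0%) depended on the scaling. The count was 2150 without 0 min library 1, 2950 without 0 min library 3, 2185 without 15 min library 1 and 2123 without 15 min library 2. It was higher, at 6412, without 15 min library 3, the library apart on the second principal component.

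The direction of change at 15 min differed by position. Outside genes, 1290 of 19207 tested regions (6.72%) were higher and 269 (1.40%) lower, with a median log2 of 0.21. Inside genes, 770 of 20082 (3.83%) were higher and 673 (3.35%) lower. At gene ends, 271 of 15010 (1.81%) were higher and 1206 (8.03%) lower, with a median log2 of -0.16. With factors set on gene ends alone, the regions at gene ends split into 593 higher and 555 lower and those outside genes into 2197 higher and 119 lower. Those inside genes split into 1345 higher and 294 lower, so their near balance also depended on the scaling. The fall at gene ends thus held relative to the other regions and not as a level. Among higher calls 88.4% lay away from gene ends, against 72.8% of regions not called (Fisher's exact test, two-sided, odds ratio 2.83, p = 3.65e-72, adjusted p = 1.64e-71 over 9 tests). Among lower calls it was 43.9% (Fisher's exact test, odds ratio 0.291, p = 8.54e-167, adjusted p = 7.69e-166). Regions are not independent replicates, so these p-values overstate the evidence.

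**Figure D2:**
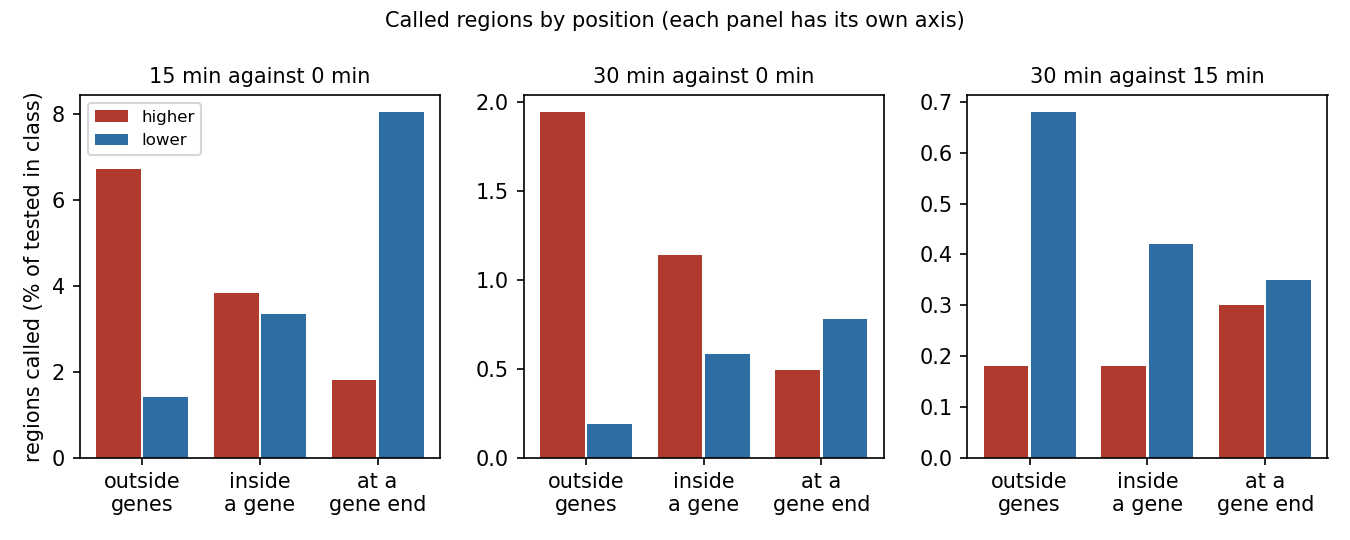
Percent of tested regions called higher (red) or lower (blue) by position, for each comparison of times, with a separate axis per panel. At 15 min 6.72% of regions outside genes were higher and 8.03% of regions at gene ends were lower, under scaling factors set on all regions; with factors set on gene ends, calls there split into 593 higher and 555 lower.

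Of the 31 gene lists, 5 were called as sets at 15 min, and 0 of these calls held with an estimated correlation (adjusted p = 0.584 to 0.699). The histone list was higher as a set (median log2 0.30; 5 of 11 measured genes called, 10 adjusted over the list alone; adjusted p = 0.584 with an estimated correlation). These 5 genes shared 3 of the 7 distinct histone regions. The shared region of the histone genes H1f4 and H2bc6 rose by 0.79 ± 0.10 and that of the linker histone gene H1f1 by 0.77 ± 0.11, and the shared region of H2bc3 and H3c3 rose by 0.35 ± 0.09 (SE, n = 3 libraries per time). Cytosolic ribosomal protein genes were higher as a set (median 0.19; 4 of 25 called, 8 adjusted over the list alone; adjusted p = 0.584 with an estimated correlation), among them Rps27a by 0.42 ± 0.10, Rpl7a by 0.36 ± 0.10 and Rpl3 by 0.27 ± 0.08. The list of MYC-driven ribosome biogenesis was higher (median 0.16; adjusted p = 0.587 with an estimated correlation) with 0 of 16 members called. The list of the mitochondrial ribosome was also higher (median 0.13; adjusted p = 0.699 with an estimated correlation), with Mrpl16 higher by 0.45 ± 0.13 and Mrps12 lower at -0.42 ± 0.12 among 24 measured. The list of imprinted and nuclear lncRNA genes was higher (median 0.16; adjusted p = 0.587 with an estimated correlation), with Snhg3, a small nucleolar RNA host gene, called at 0.33 ± 0.10 among 13.

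The set test, camera with a preset correlation, compared each list with the other genes that have a region at a gene end. Its adjusted p was 2.8e-12 for histones, 1.64e-07 for ribosomal proteins, 0.0126 for MYC-driven ribosome biogenesis and 0.0364 for each of the mitochondrial and lncRNA lists. With each shared region counted once, the 5 lists remained called, histones at adjusted p = 1.33e-07. The number of lists called was 3 without 0 min library 1, 3 without 15 min library 1 and 2 without 0 min library 3. The histone and ribosomal protein set calls held without any 1 library. Of the members named above, H1f1, H1f4 and H2bc6 were called without any 1 library. H2bc3 and H3c3 were not called without 15 min library 1 or 0 min library 3, Rps27a not without these or 0 min library 2, and Rpl7a not without 0 min libraries 1 or 3 or 15 min library 2. Rpl3 was called only without 15 min library 3 among the 9 omissions, and Mrpl16 only without 15 min library 3 or 30 min libraries 1 or 3. Mrps12 was not called without libraries 1 or 2 of 0 min or of 15 min, and Snhg3 not without 0 min libraries 1 or 3, 15 min libraries 1 or 2 or 30 min library 2. With factors set on gene ends the list medians were 0.45 for histones, 0.33 for ribosomal proteins, 0.31 for each of the MYC and lncRNA lists and 0.28 for the mitochondrial list, so their size depended on the scaling and their sign did not. The call of the mitochondrial list was lost without library 1 or 3 of 0 min or of 15 min. That of the lncRNA list was lost without library 1 or 3 of 0 min or library 1 or 2 of 15 min, and that of the MYC list without 0 min library 3.

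Single members of other lists changed at 15 min, 17 of 385 measured members of all lists being higher and 22 lower (31 and 29 adjusted over the list alone). The members named here were chosen after their values were seen, from those called without any 1 library. Id3, a BMP target that inhibits differentiation factors, rose by 1.04 ± 0.14, and Nr0b1, a pluripotency gene on the X chromosome, by 0.51 ± 0.12. Gadd45b, a growth arrest gene counted among p53 targets, fell by 1.19 ± 0.12 on the log2 scale. Bcl3 (LIF-STAT3 targets) fell by 0.66 ± 0.11, and Stip1, a co-chaperone gene, by 0.68 ± 0.14. Bnip3, a hypoxia target, fell by 0.93 ± 0.20, Gdf15, a stress-response gene, by 0.64 ± 0.13, Lmna, the lamin A gene, by 0.72 ± 0.16, and Ascl2, a trophectoderm gene, by 1.57 ± 0.38. These falls share the limit given above, that the level at gene ends depended on the scaling.

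The comparison of 30 min with 0 min asked what had changed by the later time. Besides Firre and Gm35612, a region inside Apod, which encodes a lipid-binding apolipoprotein, rose by a log2 of 2.53 ± 0.25 (SE, n = 3 libraries per time, adjusted p = 7.26e-07). Regions inside Fads3, Armc2, Gm34894 and Duox1, a gene for an enzyme that makes hydrogen peroxide, rose by 2.48 ± 0.23, 2.28 ± 0.25, 1.80 ± 0.26 and 2.19 ± 0.43. Regions outside genes rose by 1.98 ± 0.24 near Arih1, 1.78 ± 0.22 near Trps1, 1.92 ± 0.25 near Gm5784 (36.8 kb), 1.86 ± 0.35 near Gm11981 (57.8 kb) and 1.80 ± 0.33 near Cetn1, a centrin gene (21.7 kb). The calls of Duox1 (without 30 min library 2), Gm11981 (without 0 min library 1 or 30 min library 3) and Cetn1 (without 0 min library 1) were lost when 1 library was left out.

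Among regions lower at 30 min, the one inside Lag3, an immune receptor gene, fell by 1.44 ± 0.24 on the log2 scale (adjusted p = 0.00189), and its call held without any 1 library. The other 11 named falls each lost their call without at least 1 library of 0 or 30 min. They were at -1.81 ± 0.40 near Anapc10, a gene of the anaphase-promoting complex, -1.74 ± 0.41 inside Plxna2 (a semaphorin receptor), -1.60 ± 0.32 inside Myh14 (a non-muscle myosin) and -1.53 ± 0.33 inside Fam131c. At gene ends they were -1.59 ± 0.33 for Aifm2, -1.55 ± 0.34 for Prag1, -1.43 ± 0.29 for Bhlhe40, a transcriptional repressor gene, and -1.42 ± 0.34 for Megf6. Inside Gm41937 and Stap2 they were -1.48 ± 0.30 and -1.41 ± 0.29, and near Snx32, a sorting nexin gene, -1.39 ± 0.32.

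In all, 945 regions (1.74%) were called at 30 min against 0 min by edgeR, 675 higher and 270 lower (71.4% higher), and DESeq2 called 894, of which 806 were shared. The number with an unadjusted p under 0.05 was 8248. With factors set on gene ends alone, the median of all regions moved by 0.11 on the log2 scale and the calls were 1107 higher and 132 lower (89.3% higher). With no filter on low counts they were 644 higher and 470 lower (57.8% higher). The count was 171 without 0 min library 1, 475 without 0 min library 3, 1510 without 15 min library 3, 283 without 30 min library 1, 338 without 30 min library 2 and 245 without 30 min library 3, the last with 85.7% higher.

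At 30 min, regions outside genes again rose more often than they fell, 372 of 19207 (1.94%) higher and 37 (0.190%) lower. Those inside genes gave 229 higher and 116 lower. At gene ends 74 of 15010 (0.490%) were higher and 117 (0.780%) lower, a split that turned to 125 higher and 55 lower with factors set on gene ends. Of higher calls 89.0% lay away from gene ends, against 72.2% of regions not called (Fisher's exact test, odds ratio 3.12, p = 4.06e-26, adjusted p = 1.22e-25), and of lower calls 56.7% (odds ratio 0.503, p = 5.54e-08, adjusted p = 1.25e-07). The share of lower calls was 70.4% without 0 min library 1 (exact p = 0.646) and 65.7% without 30 min library 3 (exact p = 0.336), no longer past the threshold.

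Regions called at both times moved the same way, but for 1. Of the 675 regions higher at 30 min, 552 (81.8%) had been called higher at 15 min, as at Fads3, Arih1 and Trps1, where 29.0 would be shared if the calls were independent. Of the 270 lower, 171 (63.3%) had been called lower at 15 min, as at Aifm2 and Megf6, where 10.7 would be shared, and 1 region was called in opposite directions. In 20 simulations without any change, in which all libraries were redrawn and both comparisons shared the 0 min libraries, on average 0.25 and 0.10 regions were shared. The simulations called 0 to 4 regions per comparison, so a shared count near 0 was fixed by their design. They give no expected overlap for the larger number of calls made here. The correlation of the 2 sets of log2 changes across regions was 0.718, against 0.513 in the simulations, and the covariance 0.197 against 0.0641. The same 3 control libraries entered both comparisons and are too few to split, so part of the excess may come from them. The shared higher calls numbered 99 without 0 min library 1, 308 without 0 min library 3, and 204, 233 and 192 without 30 min libraries 1, 2 and 3. The shared lower calls numbered 44, 305 and 68 without 0 min libraries 1, 2 and 3, 105 and 372 without 15 min libraries 1 and 3, and 45, 57 and 24 without 30 min libraries 1, 2 and 3.

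Targets of ATF4, the factor of the integrated stress response, were lower as a set at 30 min (median log2 -0.41; 0 of 20 higher and 2 lower, 5 lower adjusted over the list alone; adjusted p = 0.699 with an estimated correlation). In this list Stc2, a stanniocalcin gene, was at -0.94 ± 0.19 and Gdf15 at -0.55 ± 0.13, and Nupr1, not called, at -0.90 ± 0.29. Cytosolic ribosomal protein genes were higher as a set (median 0.10; 1 of 25 called, 1 adjusted over the list alone; adjusted p = 0.587 with an estimated correlation) with, not called, Rpl10 at 0.31 ± 0.11 and Rpl7a at 0.24 ± 0.10. Targets of YAP and SRF were higher as a set (median 0.26; adjusted p = 0.698 with an estimated correlation) with 0 of 9 called, Tpm1, Ccn1 and Vcl, genes of the cytoskeleton and matrix, being at 0.64 ± 0.23, 0.45 ± 0.19 and 0.26 ± 0.19. Core pluripotency genes were higher as a set (median 0.07; adjusted p = 0.639 with an estimated correlation) with 0 of 11 called, and Tdgf1, Zscan10 and Utf1 were at 0.24 ± 0.10, 0.21 ± 0.11 and 0.15 ± 0.10. Histone genes were lower as a set (median -0.22; 0 of 11 called, 5 adjusted over the list alone; adjusted p = 0.826 with an estimated correlation), with H4c8 at -0.30 ± 0.09 and the shared region of H2ac8 and H2bc8 at -0.31 ± 0.10.

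The adjusted p of the set test was 0.00468 for ATF4 targets, 5.95e-05 for ribosomal proteins, 0.0265 for YAP and SRF targets and for core pluripotency, and 0.0364 for histones. With an estimated correlation 0 of the 5 calls held. With each shared region counted once, the histone call was lost (adjusted p = 0.132) and the other 4 remained. The count of lists was 3 without 30 min library 2. The core pluripotency call was lost without 0 min library 1 or 30 min libraries 2 or 3, that of YAP and SRF targets without 0 min libraries 2 or 3 or 30 min library 2, and that of histones without 30 min library 1, 0 min library 2 or 15 min library 2. The calls of ATF4 targets and ribosomal proteins held without any 1 library. With factors set on gene ends the medians were -0.30 for ATF4 targets, 0.20 for ribosomal proteins, 0.38 for YAP and SRF targets, 0.17 for core pluripotency and -0.12 for histones, with the same signs. Of single members, Gdf15 lost its call without libraries 1 or 2 of 0 min or any of 30 min and Stc2 without 0 min library 1 or 30 min libraries 1 or 3.

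The other 26 lists were not called at 30 min (adjusted p of the set test 0.0571 to 0.98). For each, members among the 3 with the smallest p at 30 min are given as log2 change ± SE, called only where stated. Among signalling targets, Id3 rose by 1.13 ± 0.14 (adjusted p = 5.43e-05) and Smad6, a BMP inhibitor gene, fell by 0.84 ± 0.22 (adjusted p = 0.0445), with Nrarp at -0.57 ± 0.18, in the list of NOTCH, TGF-beta and BMP targets (1 higher and 1 lower of 16). Nfkb1 rose by 0.58 ± 0.15 in the list of NF-kB and interferon targets (1 higher of 9), with Bst2 at -0.45 ± 0.18. LIF-STAT3 targets (0 of 10; 3 lower adjusted over the list alone) had Bcl3 at -0.35 ± 0.11, Gbx2 at -0.58 ± 0.19 and Pim3 at -0.55 ± 0.19. WNT targets (0 of 6) had Nkd1 at -0.73 ± 0.38, Lef1 at -0.27 ± 0.17 and Ccnd1 at 0.20 ± 0.13. Immediate early genes (0 of 22) had Zfp36 at -0.37 ± 0.17, Jun at 0.27 ± 0.13 and Klf6 at -0.32 ± 0.16. Id3 was called without any 1 library. Smad6 was not called without 0 min libraries 1 or 3 or any library of 30 min, and Nfkb1 was called only without 0 min library 2 or 15 min library 3.

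Stress and growth lists followed. Gadd45b fell by 0.71 ± 0.12 (adjusted p = 0.00177, called without any 1 library) in the list of p53 targets (1 lower of 17), with Tnfrsf10b at -0.48 ± 0.20 and Zmat3 at -0.28 ± 0.12. Heat shock genes (0 of 16) had Stip1 at -0.39 ± 0.13, Hspa1b at -0.33 ± 0.22 and Dnajb1 at -0.13 ± 0.13. Genes of the unfolded protein response (0 of 13) had Pdia6 at -0.41 ± 0.22, Calr at 0.19 ± 0.11 and Sdf2l1 at -0.32 ± 0.18. Glycolysis and hypoxia genes (0 of 17) had Bnip3 at -0.47 ± 0.19, Ankrd37 at -0.32 ± 0.15 and P4ha1 at -0.38 ± 0.19. Cholesterol synthesis genes (0 of 18) had Acat2 at -0.36 ± 0.16 and Sqle at -0.17 ± 0.13. Genes of G1/S and S phase (0 of 15) had Rrm2 at -0.22 ± 0.12, E2f1 at -0.23 ± 0.13 and Slbp at -0.16 ± 0.11, and genes of G2/M (0 of 17) had Aurkb at -0.28 ± 0.12, Kif20a at 0.17 ± 0.10 and Birc5 at -0.16 ± 0.12. The mitochondrial ribosome (0 of 24) had Mrpl15 at 0.34 ± 0.13, Mrps12 at -0.28 ± 0.12 and Mrpl10 at 0.25 ± 0.16, and MYC-driven ribosome biogenesis (0 of 16) had Ppan at 0.19 ± 0.11, Pes1 at 0.19 ± 0.15 and Npm1 at 0.17 ± 0.13.

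Lists of cell state and of other cell types were not called either. In the naive pluripotency list (1 higher of 15) Nr0b1 rose by 0.45 ± 0.12 (adjusted p = 0.0406; called only without 15 min libraries 2 or 3 among the 9 omissions), and Tdh and Prdm14 were at 0.19 ± 0.12 and 0.16 ± 0.11. Formative and primed genes (0 of 8) had Pou3f1 at -0.65 ± 0.31, Etv4 at 0.73 ± 0.35 and Lef1 at -0.27 ± 0.17. The list of the two-cell-like state (0 of 3) had Duxf3 at 0.45 ± 0.49, Eif1a at 0.10 ± 0.12 and Gm5662 at -0.07 ± 0.38. Primitive endoderm genes (0 of 6) had Cubn at 0.57 ± 0.26 and the shared region of Col4a1 and Col4a2 at -0.55 ± 0.32. Mesoderm genes (0 of 6) had Lefty2 at -0.13 ± 0.10, Mesp2 at -0.46 ± 0.40 and Kdr at 0.28 ± 0.32. Neuroectoderm genes (0 of 7) had Sox1 at -0.57 ± 0.30 and Pax6 at 0.63 ± 0.38. Trophectoderm genes (0 of 5) had Tead4 at -0.35 ± 0.16, Ascl2 at -0.68 ± 0.34 and Tfap2c at -0.28 ± 0.34, and markers of fibroblast feeder cells (0 of 4) had Thy1 at -0.64 ± 0.66, Twist1 at -0.40 ± 0.50 and Fn1 at -0.11 ± 0.13.

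Lists tied to Firre or to chromatin were also not called at 30 min. Neat1, a nuclear paraspeckle RNA gene, rose by 0.34 ± 0.09 (adjusted p = 0.0456; called only without 15 min libraries 1, 2 or 3 among the 9 omissions) in the list of imprinted and nuclear lncRNA genes (1 higher of 13), with Miat at -1.12 ± 0.54 and Malat1 at 0.25 ± 0.15. In a list of possible Firre contact genes, written from memory and not checked against a source, Slc25a12, Ppp1r10 and Eef1a1 were at 0.57 ± 0.17, 0.22 ± 0.11 and -0.06 ± 0.10 (0 of 3 called, 1 higher adjusted over the list alone). At 15 min Ppp1r10 was called higher at 0.41 ± 0.11, though not without 0 min libraries 1 or 3 or 15 min library 1. Genes of Firre binding partners and the nuclear matrix (0 of 9) had Lmna at -0.29 ± 0.16, Lmnb1 at -0.24 ± 0.14 and Safb at -0.19 ± 0.15. Polycomb and heterochromatin genes (0 of 14) had Suz12 at 0.24 ± 0.12, Mtf2 at -0.23 ± 0.12 and Rnf2 at -0.31 ± 0.24. Over the 385 measured members of all lists, 5 were higher and 4 lower at 30 min (6 and 17 adjusted over the list alone). Signs of median, mean and set test differed in 30 of the 93 list tests and in 0 of those called.

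The step from 15 to 30 min asked which early changes went on and which turned back. Away from Firre and Gm35612, the 12 named falls were all in regions called higher at 15 min. The same 15 min libraries entered both calls, which favours this match even without change. The region near Actr5 fell by 2.79 ± 0.38 on the log2 scale (SE, n = 3 libraries per time, adjusted p = 0.00014) and that near Slc45a3 by 2.13 ± 0.33. Falls near Rrp12, a ribosome assembly gene, near Myo10, a myosin gene, and near Far1, a gene of ether lipid synthesis, were 1.91 ± 0.27, 1.76 ± 0.21 and 1.75 ± 0.28. The region inside Eml6 fell by 1.75 ± 0.28 and was still called higher at 30 than at 0 min (log2 1.70 ± 0.39, adjusted p = 0.0216). Those near Arhgap5, near St14, a membrane protease gene, and inside Gm32525 fell by 1.74 ± 0.18, 1.69 ± 0.22 and 1.67 ± 0.28. These 9 were called without any 1 library, though DESeq2 did not call Actr5 or Slc45a3. The region inside Ripor3 fell by 1.89 ± 0.37, that near Lamc1, a laminin gene, by 1.76 ± 0.38 and that inside Capn12, a calpain gene, by 1.69 ± 0.41. These 3 calls were lost under DESeq2 and without at least 1 library.

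**Figure D3:**
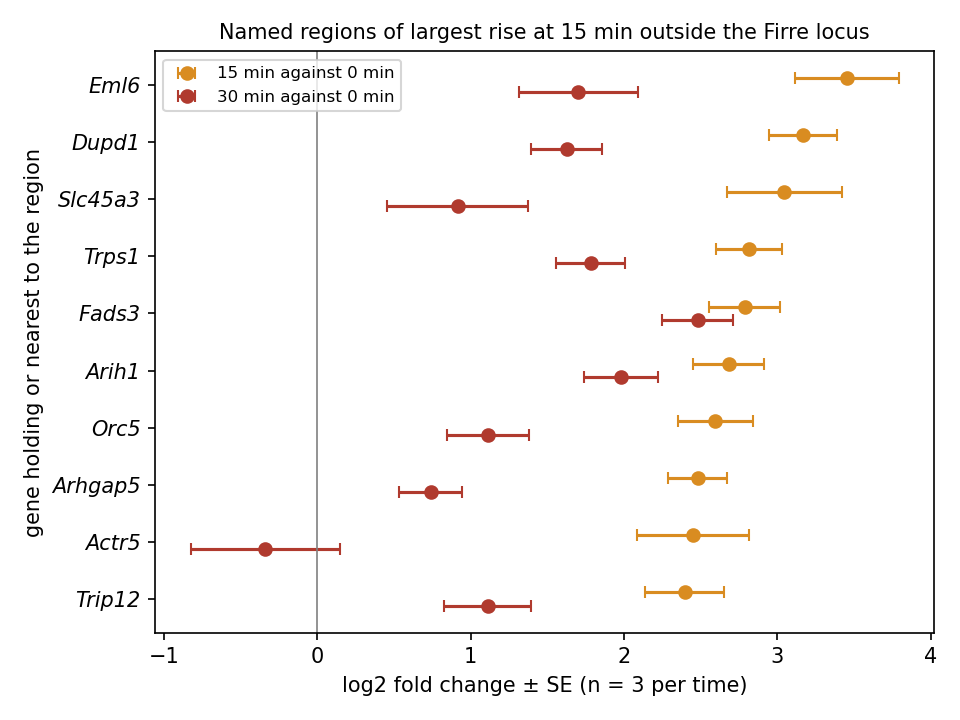
Log2 fold change against 0 min at 15 min (orange) and 30 min (red) for the 10 regions with the largest rise at 15 min outside the Firre locus among those that met the naming rule (a mean of at least 20 counts over the 0 and 15 min libraries, groups not overlapping, a gene counted once), labelled by the gene holding or nearest to each, with bars for SE (n = 3 libraries per time). The region near Actr5 was at 2.45 at 15 min and -0.34 at 30 min, and that inside Fads3 at 2.79 and 2.48. Choosing regions by their rise at 15 min favours a smaller value at 30 min.

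Regions that rose from 15 to 30 min mostly stood below their 0 min level at 15 min, a pattern that the shared 15 min libraries also favour. The one inside Gm34121 rose by 1.95 ± 0.27 after -1.97 at 15 min, and that near Pitpnb, a lipid transfer protein gene, by 1.49 ± 0.24 after -1.50. Regions inside Ghdc and Chid1 rose by 1.47 ± 0.22 and 1.34 ± 0.17. These 4, with Firre and Gm35612, were called without any 1 library. The other 6 named rises lost their call without at least 1 library. Outside genes, they were 1.52 ± 0.33 near Ubxn1 and 1.40 ± 0.27 near Arf1, a vesicle traffic gene. Also outside genes, they were 1.38 ± 0.33 near Cask, a scaffold kinase gene, and 1.3 ± 0.30 near Gopc. At gene ends they were 1.27 ± 0.26 for Terf2ip, a telomere protein gene, and 1.28 ± 0.25 for Tpm1, the tropomyosin gene.

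In all, 382 regions (0.700%) were called at 30 min against 15 min by edgeR, 116 higher and 266 lower (30.4% higher), and DESeq2 called 469, with 356 shared. The number with an unadjusted p under 0.05 was 5230. With factors set on gene ends alone the calls were 60 higher and 272 lower (18.1% higher). Of the 2331 regions higher at 15 min, 221 were then lower and 9 higher, and of the 2148 lower at 15 min, 81 were then higher and 0 lower. The 15 min libraries entered both comparisons with opposite sign, so part of this turning back is expected without change. How large that part is was not simulated. The share higher was 16.1% without 15 min library 1 and 45.1% without 15 min library 3. The count was 193 without 15 min library 1, 202 without 15 min library 2, 183 without 30 min library 1, 154 without 30 min library 2 and 222 without 30 min library 3. It was higher, at 548, without 15 min library 3.

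Outside genes, 34 regions were higher and 130 lower from 15 to 30 min, inside genes 37 and 84, and at gene ends 45 and 52 (21 and 51 with factors set on gene ends). Of lower calls 80.5% lay away from gene ends, against 72.3% of regions not called (Fisher's exact test, odds ratio 1.57, p = 0.00303, adjusted p = 0.00454), and of higher calls 61.2% (odds ratio 0.603, p = 0.00925, adjusted p = 0.0119). The share of lower calls was past the threshold of 0.05 neither without 15 min libraries 1 (79.0%) or 2 (71.6%), nor without 30 min libraries 1 (78.3%), 2 (71.7%) or 3 (74.4%), nor without 0 min library 3 (79.1%). That of higher calls was not past it without 15 min libraries 1 (61.3%) or 2 (68.9%) or without 30 min libraries 1 (65.0%), 2 (70.6%) or 3 (62.1%).

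Histone genes fell together from 15 to 30 min. Of 11 measured histone genes 10 were called lower (11 adjusted over the list alone), which is 6 of 7 distinct regions, with a list median of -0.51. The shared region of H1f4 and H2bc6 fell by 1.01 ± 0.10 on the log2 scale (adjusted p = 1.91e-06) and that of H1f1 by 0.73 ± 0.11. The shared region of H2ac8 and H2bc8 fell by 0.61 ± 0.10, that of H2ac6 and H2bc4 by 0.51 ± 0.11, that of H2bc3 and H3c3 by 0.47 ± 0.09 and that of H4c8 by 0.50 ± 0.09. The gene not called, H1f0 at -0.31 ± 0.11, encodes a linker histone made outside S phase. The set test gave adjusted p = 3.82e-40, or 1.1e-24 with each shared region counted once, and adjusted p = 0.0774 with an estimated correlation, so that call was lost. The rotation test fry, which asks only whether the genes move one way, gave adjusted p = 0.0382. The set call held without any 1 library, as did the calls of H1f1, H1f4 and H2ac8, while those of H2ac6 and H2bc3 were lost without 15 min library 1 or 30 min library 1 and that of H4c8 without 30 min library 1.

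**Figure D4:**
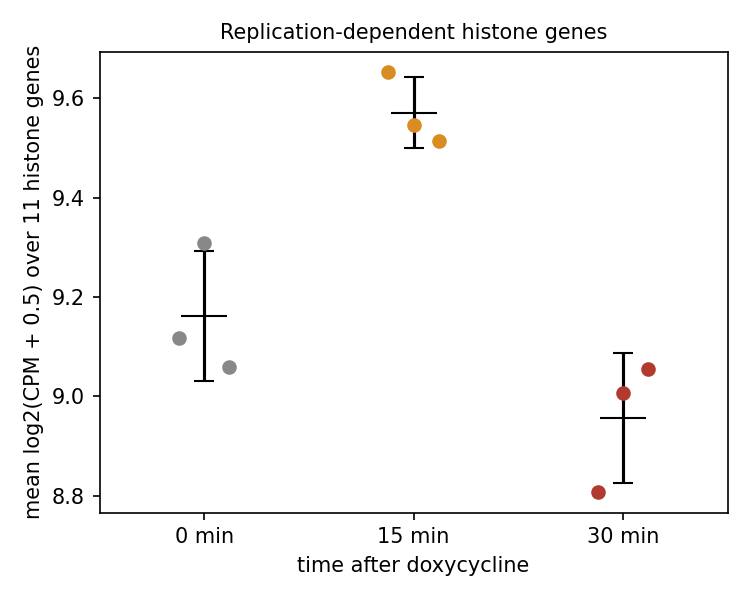
Mean log2 CPM over the 11 measured histone genes, one point per library, with bars for the mean and SD of 3 libraries at each time after doxycycline. The 3 libraries at 15 min (9.51 to 9.65) lay above the 3 at 0 min (9.06 to 9.31) and the 3 at 30 min (8.81 to 9.05).

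Other lists called from 15 to 30 min were ribosomal protein genes (median -0.10, adjusted p = 0.0176) and ATF4 targets (median -0.16, adjusted p = 0.0258), both lower, with 0 of 25 and 0 of 20 members called. Each had adjusted p = 0.699 with an estimated correlation. With factors set on gene ends the medians were -0.15 and -0.21, and that of histones -0.57. The call of ribosomal proteins was lost without 15 min library 1, and that of ATF4 targets without 15 min library 3 or 30 min library 3. Tpm1 (YAP and SRF targets) and Nfkb1 (NF-kB and interferon targets) were the members called higher, at 1.28 ± 0.25 and 0.68 ± 0.15, the first not without 30 min library 2 and the second not without libraries 1 or 2 of 15 min or any library of 30 min. Over the 385 measured members, 2 were higher and 10 lower (4 and 12 adjusted over the list alone).

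Firre is an X-linked gene, so the X share of calls was compared with that of other tested regions. At 15 min 104 of 4479 called regions (2.32%) lay on the X chromosome, against 3.8% of those not called (Fisher's exact test, odds ratio 0.602, p = 1.05e-07, adjusted p = 1.89e-07), and 9 of the 104 lay at Firre or Gm35612. At 30 min the share was 3.07% against 3.69% (exact test, odds ratio 0.826, p = 0.382, adjusted p = 0.382), and from 15 to 30 min 2.62% against 3.69% (odds ratio 0.702, p = 0.338, adjusted p = 0.38). Of these X calls, 9 of 29 and 8 of 10 lay at Firre or Gm35612. With the regions of those 2 genes left out, an alternative chosen after seeing the data, the X shares were 2.13%, 2.14% and 0.535% (exact p = 1.11e-09, 0.0106 and 0.000241, unadjusted). The 2 later comparisons were then past the threshold too. These tests were not matched on count level. The median X region, tested or not, had a mean of 2.11 counts, against 2.22 to 71.3 on the other chromosomes. Calls at 15 min were rarer at low counts. Away from gene ends, 196 of 11905 regions with mean counts of 4.9 to 13.4 were higher and 52 lower. At mean counts of 79.9 to 11585.6, 844 of 6884 were higher and 427 lower. The lower X shares therefore do not settle whether X regions responded less. The share at 30 min was 7.6% without 0 min library 1 (exact p = 0.0139, the opposite direction) and 2.48% without 0 min library 2 (exact p = 0.0216). All tested Firre regions stayed called while the calls fell to 171 without 0 min library 1, so the locus weighs more in that share. The share at 30 min was 4.21% without 0 min library 3 and 4.59%, 4.44% and 5.71% without 30 min libraries 1, 2 and 3, not past the threshold. From 15 to 30 min the share was 3.96% without 15 min library 2 and 4.92% and 4.55% without 30 min libraries 1 and 2.

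Over the whole time course, 3283 regions were called by a single test for any change, Firre among them, and DESeq2 called 3038, with 2847 shared. The number with an unadjusted p under 0.05 was 11279. The count was 1490 without 0 min library 1, 2066 without 0 min library 3, 1918 without 15 min library 1, 1977 without 15 min library 2 and 4987 without 15 min library 3.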

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

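Among the Firre regions and the regions and list members named for a change against 0 min, the effects at 15 and at 30 min differed for 22 regions by the test of 30 against 15 min, which called 382 of all tested regions. They also differed for 3 gene lists. At Firre, 6 regions were further up at 30 min, by a log2 of 1.39 (bidir_167537), 1.38 (bidir_167535), 1.12 (bidir_167536), 1.40 (bidir_167538), 1.59 (bidir_167539) and 1.49 (bidir_167541). Beside it the Gm35612 regions were up by 1.09 (bidir_167533) and 1.27 (bidir_167534). Regions that had risen at 15 min were lower at 30 min: Eml6 (-1.75), Dupd1 (-1.54), Slc45a3 (-2.13), Trps1 (-1.03), Orc5 (-1.48), Arhgap5 (-1.74), Actr5 (-2.79) and Trip12 (-1.28). The shared 15 min libraries favour such a fall, so these values are not independent of the rise. Gm34121 (1.95), Tpm1 (1.28) and Nfkb1 (0.68) were higher at 30 than at 15 min, and Gm41937 (-1.32), H4c8 (-0.50) and H2ac8 (-0.61) lower. The lists were histones (median -0.511), ATF4 targets (-0.162) and cytosolic ribosomal proteins (-0.102). In this part the tests of scaling, of library shares, of count level at 3' ends, of S phase and of random lists were chosen after the result was seen. The others were written before their own result was seen. The patterns below were themselves found in these data, so their tests are not independent of them.

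The first pattern is the rise of regions away from gene ends relative to regions at gene ends at 15 min. The medians differed by 0.281 on the log2 scale, which no single factor per library can produce, and by at least 0.182 in each of 4 equal bins of mean count, so count level alone is argued against. The share of reads at gene ends was 45.0 ± 2.27% at 15 min and 47.7 ± 1.47% at 0 min (exact permutation p = 0.2, the smallest possible being 0.1). At 30 min it was 45.2 ± 0.74% (exact permutation p = 0.1 against 0 min). Variation between libraries cannot be told apart from time with 3 libraries each. Whether gene ends themselves fell is also open: 48.3% of their calls were lower with factors set on gene ends, against 81.7%, and that scaling fixes their median. A response to the transgene, to doxycycline itself or to handling may each underlie the pattern, and none of these was tested.

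The second pattern is the rise of regions outside genes at 15 min, as near Slc45a3 and Actr5, and a candidate explanation is transcription running past the 3' ends of genes. The idea came from the positions of the largest changes; of regions 1 to 15 kb outside a gene, 249 of 1614 (15.4%) beside inferred 3' ends were higher and 140 of 2283 (6.13%) beside inferred 5' ends, a ratio of 2.52 (Fisher's exact p = 4.16e-21), with gene orientation inferred from the stronger end for 9080 of 35108 genes. Count level is argued against by an odds ratio of 2.62 (2.10 to 3.27) within these bins, and a single pair of libraries by a median log2 difference of at least 0.581 in each held-out pair. Regions over 50 kb from any gene end were called higher in 195 of 3871 cases (5.04%), but their median log2 was 0.33. That was above the median beside 3' ends (0.27) and 5' ends (0.09), so the shift was not confined to regions beside 3' ends. These medians were not matched on count level (median mean count 19.7 far away, 31.3 beside 3' and 26.1 beside 5' ends). They therefore do not settle how much of the shift transcription past 3' ends accounts for. Of the 130 regions outside genes called lower from 15 to 30 min, 74 lay beside inferred 3' ends, 7 beside 5' ends and 1 far away. The others outside genes were in none of these classes, and 84 more falls lay inside genes and 52 at gene ends. The odds ratio of a fall was 14.6 (6.63 to 32.1) for 3' against 5' ends. The shared 15 min libraries favour a fall where a rise was called, so this ratio is not independent of the rise. At 30 against 0 min 40 regions beside 3' ends and 40 beside 5' ends were higher.

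The third pattern is the rise and fall of histone genes, whose median from 15 to 30 min was -0.511, outside the central range of 10000 random lists matched on mean count (-0.101 to 0.116). Genes of G1/S and S phase had a median of -0.005 over the same step, which argues against another share of cells in S phase as far as these genes report it. Other coding genes of at most 1 kb (59 measured) had a median of -0.012, which argues against short genes in general. These tests leave a change of histone transcription with time after doxycycline as a hypothesis, found and tested on the same data. The 11 genes share 7 regions, 6 of them called, and the set call was lost with an estimated correlation. The random lists were not matched on shared regions or on the correlation between genes, estimated at 0.438 for histones. Their range may therefore be too narrow for such a list.

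Other splits of the libraries were fitted in the same way. For 15 against 0 min the real split gave 4479 regions and the highest other 367, for 30 against 0 min 945 and 1, and for 30 against 15 min 382 and 0. In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For any change over time 1 of 50 splits drawn for the 9 libraries gave as many, the real one with 3283. The highest other, 2078, kept the 0 min libraries together and mixed 15 with 30 min. So a random division of the libraries seldom gives as many calls. Splits cannot tell time apart from handling shared by the libraries of a time.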

How the results depend on the processing

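Of 339 values of the main results under an alternative, 261 kept their direction and their side of the threshold, or a count within 1.5 times. The 98 named regions that were called gave 1744 values, of which 1601 were the same, 143 were no longer called and 0 reversed, and 63 regions were called in every alternative. Where 1 of 3 libraries was left out, the remaining 2 share the spread pooled over all groups.

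Leaving out 1 library moved the called regions between 2123 and 6412 at 15 min, 171 and 1510 at 30 min, 154 and 548 from 15 to 30 min and 1490 and 4987 for any time. The share away from gene ends for higher and lower calls lay between 87.0 and 90.0% and 37.0 and 50.4% at 15 min. It lay between 87.2 and 90.6% and 42.9 and 70.4% at 30 min, and between 47.4 and 70.6% and 71.6 and 81.7% from 15 to 30 min, where lower calls reversed without 15 min library 2 (71.6%) or 30 min library 2 (71.7%). The X share lay between 1.96 and 2.48%, 2.48 and 7.6% (reversed at 7.6% without 0 min library 1) and 2.55 and 4.92%. In that reversal the Firre regions stayed called among only 171 calls, so the locus held a larger part of them. Shared higher calls lay between 99 and 782 and shared lower calls between 24 and 372. Lists called lay between 2 and 5 at 15 min, 3 and 5 at 30 min and 2 and 4 from 15 to 30 min. Firre regions called lay between 5 and 7 from 15 to 30 min and stayed at 7 at the other times. Fewer libraries were fitted in each. The highest counts of called regions (6412, 1510, 548 and 4987) all came without 15 min library 3, the library apart on the second principal component. The cause of these higher counts was not tested. For the other values, beyond the fewer libraries and the weight of the Firre regions in the X share, the cause was not tested either.

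Without the filter the X share passed the threshold at 30 min (2.42%) and from 15 to 30 min (2.93%), and 303 lower calls were shared; the cause was not tested. The share of lower calls away from gene ends from 15 to 30 min reversed (80.5%), since the regions added to those not called lay mostly away from gene ends. The DESeq2 test gave an X share of 1.92% from 15 to 30 min, past the threshold, and with gene ends within 500 bp 75.9% of higher calls lay away from them, no longer past it; the causes were not tested. With windows that overlap no other, 4 Firre regions were called at 15 and 4 at 30 min, since fewer were tested. With an estimated correlation 0, 0 and 0 lists were called, also with each region once (0, 0 and 0), since the main test presets it. With fry, which tests each list against no change and not against other genes, 0, 0 and 1 were called; the cause was not tested. With the Firre and Gm35612 regions left out, the X share was 2.14% at 30 min and 0.535% from 15 to 30 min, both past the threshold, since 9 of 29 and 8 of 10 X calls lay there. These regions and counting a region once were alternatives chosen after seeing the data.

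The replicate number as a block gave 4804, 1107, 421 and 3635 regions. Of 9 same-number pairs, 2 had a residual correlation over 0.1 (-0.049 to 0.18), and 4 of 9 libraries were closest to one of their own number, so the numbers were not used as pairs. Depth limits what can be called: the median region had a mean of 3.00 counts, and 119990 regions were too low to test.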

Other observations

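Regions over transfer RNA genes were mostly not called. Of 172 tested windows 0 were higher and 3 lower at 15 min (median log2 -0.22), and 1 was higher from 15 to 30 min (median 0.20). Windows over microRNA genes gave 2 higher and 6 lower of 80 at 15 min, those over small nuclear RNA genes 0 of 23 called, and those over small nucleolar RNA genes 1 higher of 16. At 30 against 0 min 1 transfer RNA window was higher and 0 lower (median 0.00), 2 microRNA windows were higher and 0 lower (median -0.11), and 0 windows of the other 2 kinds were called.

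Chromosome 17 held 1128 regions, or 11.9 per Mb, against 51.6 per Mb on the X chromosome and 71.6 per Mb on chromosome 2. A region lay at an end of 37.4% of its coding genes, against 59.7% on chromosome 2, and the median region there had a mean of 71.3 counts, against 3.11. Results on chromosome 17, as for Cdkn1a or Hspa1b, therefore rest on fewer and stronger regions than elsewhere.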
